A study of Homo sapiens with 18 samples.

How the data were processed

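The deposited values are linear signal intensity, 1 per probe set and array, made with MAS5 per the submitters' processing notes, which give no version. Leaving out the 2 percent of probe sets at either end, the mean was 500.0 on every array. Detection calls, scanner images and scan dates were not among the sources used here, so that batches could not be examined. Per the labels, RNA was reverse transcribed with random hexamers and labelled with the Affymetrix Whole Transcript Sense Target kit. That kit is made for gene and exon arrays and not for this 3' expression array, so that the labelling is uncertain.

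Values were taken as log2(value + 16) without further scaling, since the array medians differed by 0.465 on the log2 scale, under the 0.5 set for scaling. The 62 control probe sets were left out. A probe set was kept if it lay above the median of its own array on at least 2 of the 18 arrays, which 36308 did. A gene was represented by the probe set of that gene alone with the highest mean, which gave 15412 genes. Gene symbols came from the platform annotation: 41097 probe sets had 1 symbol, 1801 several and 11721 none.

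Tests were done in R 4.3.3 with limma 3.58.1: a linear model with 1 mean for each of 9 groups over all 18 arrays (9 residual degrees of freedom), moderated statistics with an intensity trend, 2-sided, and Benjamini-Hochberg adjustment over the genes tested in a contrast with a threshold of 0.05. The mean of the lines averages the 3 differences within lines. Differences between lines were tested with the moderated F statistic. Replicate numbers did not pair the arrays, so that no pairing was modelled. Gene lists were tested with camera in limma at its preset correlation of 0.01 between genes, against all other genes, with adjustment over 27 lists, and again with the correlation estimated from the data. The counts of list members adjusted over the list alone use the same statistics.

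The lists were cancer-testis antigens, germline genes under promoter methylation, interferon response, MHC class I and antigen processing, MHC class II, imprinted genes, genes often methylated in lung cancer, HOX genes, p53 targets, cell cycle G2/M and mitosis, DNA replication and S phase, histone genes, DNA methylation machinery, histone deacetylases and partners, neuronal genes, metallothioneins, cholesterol synthesis, unfolded protein and amino acid stress response, heat shock response, epithelial markers, mesenchymal markers, lung epithelial lineage, leukocyte markers, fibroblast and endothelial markers, ribosomal protein genes, reference genes and NF-kB inflammatory genes. They were fixed before the data were examined, as were the model, the filter, the processing alternatives and the rule for naming genes. 8 tested genes are members of more than 1 list, and 7 of 842 entries matched no probe set.

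Genes named as examples come from a fixed rule. For each contrast averaged over the lines these are the 10 largest rises and the 5 largest falls past the threshold with 1 direction in all 3 lines. For each line against untreated they are the 5 largest rises and 3 largest falls whose treated arrays all lie beyond both untreated arrays. For each list they are the 4 members with the lowest adjusted p, and for each test between lines the 5 genes with the lowest p. Also in the rule are DNMT1, DNMT3A, DNMT3B, UHRF1, CDKN1A, CDKN2A, CDH1, MAGEA4, DAZL, HOXA2 and HOXA10, of which HOXA10 was not among the tested genes. A few results that the rule gives are not reported here. Of the genes this gives, the text names mainly those whose call did not depend on a single array.

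The procedure was tested on simulated data of the same size with known changes. Of 100 genes set to a log2 change of 1, the model called 59 percent in the right direction in A549, 59 in H1993, 63 in H2073 and 87 for the mean of the lines. At a log2 change of 2 these were 86, 85, 88 and 99 percent. Unchanged genes made up 4.17 to 4.71 percent of the calls. Of 27 lists, only that with members shifted by 0.5 passed, which says little about lists with correlated members.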

Results

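Gene expression was measured in 3 established non-small cell lung cancer lines on Affymetrix human genome-wide expression arrays of 54675 probe sets, 18 arrays in all. A549 is a lung adenocarcinoma line. H1993 and H2073 are lung adenocarcinoma lines known to come from the same patient. Each line was left untreated, given 0.5 µM decitabine (Aza-dC), a nucleoside analogue that traps DNA methyltransferases, for 6 days, or given Aza-dC followed by 24 h of 100 ng/ml trichostatin A (TSA), an inhibitor of histone deacetylases. The doses are worded for A549 and are attached to every sample. Every group held n = 2 arrays. Nothing in the labels says that they came from separate cultures, so the replicates may be technical. The array median lay between 58.6 and 87.0 signal units, and the replicates of a group correlated across genes, which are not independent of each other, with Pearson's r from 0.974 to 0.987. Untreated H1993 and H2073 resembled each other more closely across genes (r = 0.871) than either resembled A549 (r = 0.820 and 0.841). The series is the expression part of a genome-wide study of CpG island methylation in non-small cell lung cancer. Methylation and acetylation were not analysed here. Signals below are means ± SD of n = 2 arrays. Changes are log2 differences ± the standard error (SE) from limma, over n = 2 arrays per group within a line or 6 per group for the mean of the 3 lines, and p for genes and gene lists is adjusted over the 15412 genes or the 27 lists tested, or over those tested in an alternative.

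Aza-dC alone was followed by higher levels of genes that are normally active in germ cells. MAGEA4, a cancer-testis antigen, rose in A549 from a signal of 12.2 ± 6.11 to 1356 ± 127, a log2 change of 5.62 ± 0.46 (adjusted p = 1.23e-07). DAZL, an RNA-binding protein needed for germ cell development, rose in A549 from 15.8 ± 1.05 to 482 ± 32.5 (log2 change 3.97 ± 0.56), and the sperm protein gene SPANXB1 from 62.2 ± 6.39 to 2609 ± 327 (5.07 ± 0.42). In H1993 MAGEA4 (0.11 ± 0.46), DAZL (-0.07 ± 0.56) and SPANXB1 (-0.36 ± 0.42) did not pass. The difference between lines passed for each (adjusted p = 3.90e-05, 0.00593 and 3.27e-06). Over the 3 lines 10 of 21 cancer-testis antigens past the filter rose and 11 did not pass (15 rose adjusted over the list alone). The median was 0.84 (adjusted p = 1.03e-07, 0.00235 with an estimated correlation). Silent genes can pass the filter through treated arrays alone, which favours rises in this and the germline list. MAGEB2 (1.65 ± 0.18), SSX1 (1.13 ± 0.16) and, outside the list, the testis-enriched LY6K (1.92 ± 0.13) rose. The list median was 1.67 in A549, where 11 members rose, 0.97 in H2073, where 6 rose, and 0.08 in H1993, where limma passed 0 members and 2 had an unadjusted p under 0.05. The shift in H1993 was lower than in A549 (adjusted p = 1.44e-07) and H2073 (adjusted p = 0.00555), also with an estimated correlation (0.00216 and 0.0385). Of 20 germline genes under promoter methylation, 8 rose, 1 fell and 11 did not pass (9 rose and 1 fell adjusted over the list alone), with a median of 0.50 (adjusted p = 0.00261, 0.0222 with an estimated correlation). Without A549 that median was 0.20 and did not pass (adjusted p = 0.175), nor did the 0.11 with the filter at the 75th percentile (adjusted p = 0.217). The piRNA pathway genes GTSF1 (1.90 ± 0.29) and MAEL (1.80 ± 0.27) were among those that rose.

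Interferon response genes rose in H2073. The antiviral GTPase MX1 went from 382 ± 117 to 7412 ± 523 (log2 change 4.25 ± 0.29, adjusted p = 1.28e-08), the interferon-induced IFI27 from 2557 ± 4.25 to 33893 ± 5255 (3.71 ± 0.32) and IFI44L from 94.0 ± 27.9 to 2166 ± 486 (4.32 ± 0.30). In H2073 34 of 44 members of the interferon list rose and 10 did not pass (37 rose adjusted over the list alone), with a median log2 change of 1.81 (adjusted p = 2.47e-44, 6.68e-05 with an estimated correlation). In A549 9 rose and 2 fell (median -0.02), and in H1993 2 rose and 3 fell (median -0.14). The list differed between H2073 and A549 (adjusted p = 3.96e-29, 0.000402 with an estimated correlation) and between H2073 and H1993 (adjusted p = 1.06e-42, 7.83e-05 with an estimated correlation). In the mean of the lines 26 rose, 1 fell and 17 did not pass (32 rose and 1 fell adjusted over the list alone; median 0.54; adjusted p = 1.68e-17, 0.00235 with an estimated correlation). Over the lines other than H2073 the median was -0.08 and the list did not pass. Genes of MHC class I and antigen processing rose there too. The immunoproteasome subunit PSMB9 rose in H2073 from 369 ± 0.348 to 4020.3 ± 587 (3.38 ± 0.20), the peptide transporter TAP1 by 2.67 ± 0.16 and HLA-B by 1.20 ± 0.13. In H2073 15 of 20 members rose (16 rose and 1 fell adjusted over the list alone; median 1.16), more than in A549 (adjusted p = 3.25e-15, 0.00349 with an estimated correlation) or H1993 (adjusted p = 3.10e-17, 0.00306 with an estimated correlation). The mean of the lines had 13 members that rose (14 rose adjusted over the list alone), a median of 0.34 and adjusted p = 6.29e-10, 0.00963 with an estimated correlation, and a median of -0.04 without H2073, which did not pass. BST2, an interferon-induced antiviral membrane protein, rose beyond H2073, by 2.23 ± 0.33 in A549 and by 2.04 ± 0.19 over the 3 lines.

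Cell cycle genes rose in A549. CDK1, the kinase that drives entry into mitosis, went from 4893 ± 288 to 15919.5 ± 803 (log2 change 1.70 ± 0.10, adjusted p = 4.12e-09). Its partner CCNB1 rose by 1.22 ± 0.11, the replicative helicase subunit MCM4 by 1.49 ± 0.11 and the ribonucleotide reductase subunit RRM2 by 1.63 ± 0.11. All 41 measured G2/M and mitosis genes rose in A549 (41 rose adjusted over the list alone; median 1.12), with adjusted p = 3.21e-42, 0.00879 with an estimated correlation. The median was 0.10 in H1993 and 0.15 in H2073, each below A549 (H1993 minus A549 adjusted p = 4.28e-32, 0.0299 with an estimated correlation; H2073 minus A549 adjusted p = 3.96e-29, 0.0324 with an estimated correlation). Over the 3 lines 36 of 41 rose and 5 did not pass (39 rose adjusted over the list alone; median 0.47, adjusted p = 1.58e-27, 0.0232 with an estimated correlation), among them HMMR (0.97 ± 0.10) and the spindle midzone protein PRC1 (0.57 ± 0.06). For DNA replication and S phase, 30 of 39 genes rose in A549 (35 rose and 1 fell adjusted over the list alone; median 0.89; adjusted p = 7.48e-31, 0.00139 with an estimated correlation). The list was again above H1993 (adjusted p = 2.43e-29, 0.00216 with an estimated correlation) and H2073 (adjusted p = 8.29e-20, 0.00376 with an estimated correlation). In the mean of the lines 26 rose and 13 did not pass (31 rose adjusted over the list alone; median 0.33; adjusted p = 1.40e-16, 0.00705 with an estimated correlation), and the median of 0.07 without A549 did not pass. Among the genes that maintain methylation, UHRF1 rose in A549 by 1.51 ± 0.12 and DNMT1 by 0.58 ± 0.11.

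**Figure D1:**
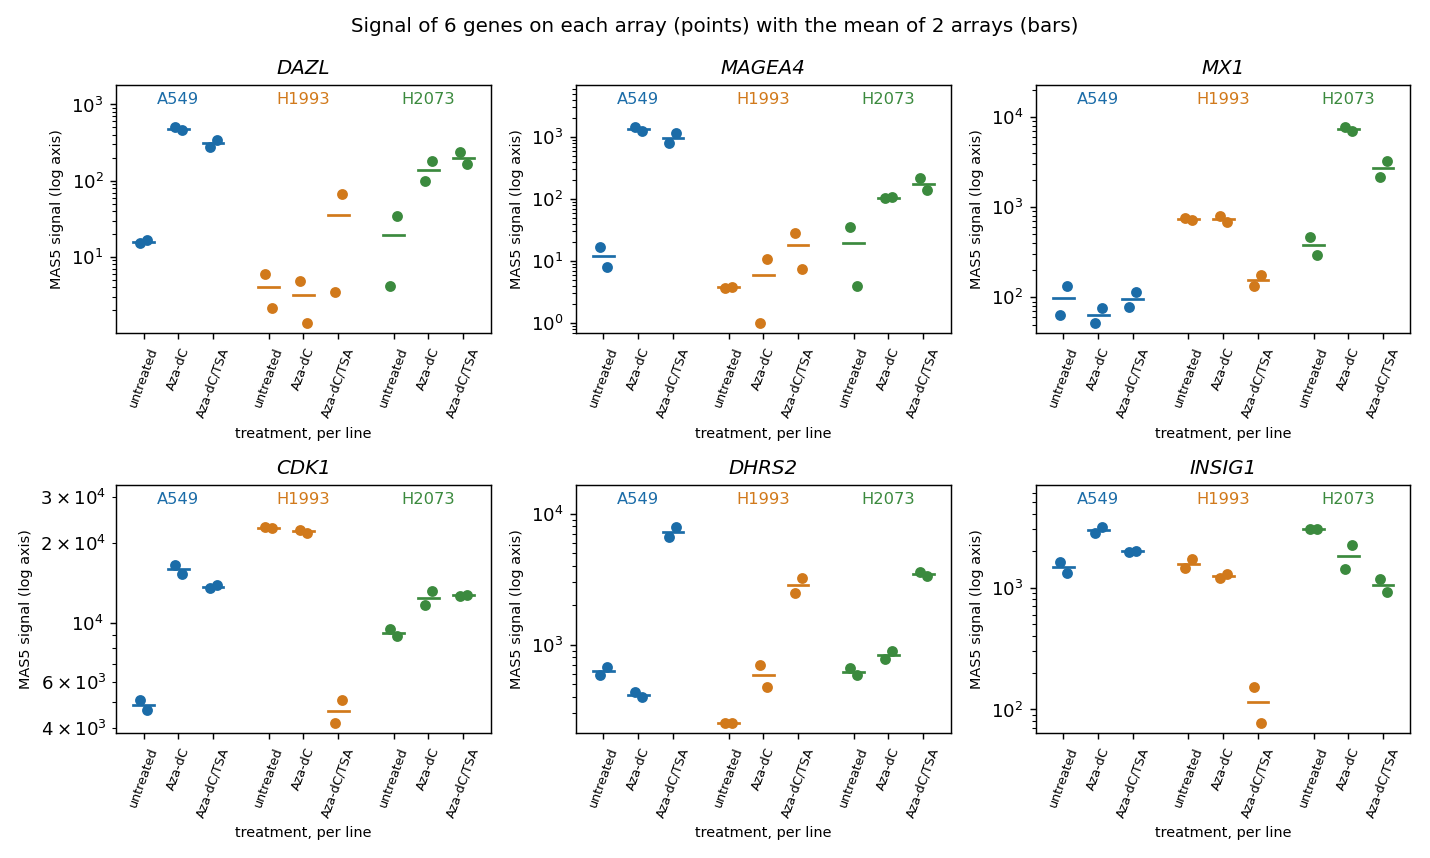
MAS5 signal on a log axis of 6 genes on each of the 18 arrays (points), by line and treatment, with the mean of n = 2 arrays (bars). MAGEA4 in A549 rose from 12.2 to 1356 with Aza-dC, MX1 in H2073 from 382 to 7412, and CDK1 in H1993 fell from 22910.1 to 4644 with Aza-dC/TSA.

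Stress response genes fell in A549. TRIB3, a pseudokinase induced by amino acid shortage, fell from 13888 ± 635 to 2681 ± 94.5 (log2 change -2.37 ± 0.11), STC2 by 2.28 ± 0.17 and the transcription factor ATF4 by 1.05 ± 0.10. In A549 14 of 27 genes of the unfolded protein and amino acid stress response fell and 5 rose (5 rose and 17 fell adjusted over the list alone; median -0.50; adjusted p = 9.80e-08, 0.00719 with an estimated correlation). That was lower than in H1993 (adjusted p = 4.95e-07, 0.0129 with an estimated correlation). The difference from H2073 (adjusted p = 0.00209) had adjusted p = 0.0585 with an estimated correlation. In the mean of the lines 3 rose, 11 fell and 13 did not pass (5 rose and 12 fell adjusted over the list alone; median -0.14; adjusted p = 1.49e-05, 0.0167 with an estimated correlation), and the median of 0.03 without A549 did not pass. DDIT4, an inhibitor of mTOR signalling, fell over the 3 lines (-0.75 ± 0.06). Of 13 heat shock genes, 9 rose and 4 did not pass (10 rose adjusted over the list alone; median 0.39; adjusted p = 5.90e-08, 0.00440 with an estimated correlation), and the chaperone HSPH1 rose in A549 by 1.40 ± 0.12. Cholesterol synthesis genes rose in A549, 10 of 19 (14 rose adjusted over the list alone; median 0.55; adjusted p = 2.45e-08, 0.00479 with an estimated correlation), as did SQLE (0.76 ± 0.13) and ACAT2 (1.29 ± 0.12). In H2073 4 fell (6 fell adjusted over the list alone; median -0.20; adjusted p = 0.00472, adjusted p = 0.0849 with an estimated correlation), and the difference from A549 passed (adjusted p = 4.19e-11, 0.00247 with an estimated correlation). In the mean of the lines 5 rose and 14 did not pass (7 rose adjusted over the list alone; median 0.17; adjusted p = 0.00311, adjusted p = 0.0560 with an estimated correlation), and the median was -0.03 without A549. Of 7 metallothioneins, which bind zinc and copper, 4 rose and 3 did not pass (6 rose adjusted over the list alone; median 0.30; adjusted p = 0.000413, adjusted p = 0.123 with an estimated correlation), with MT1F at 0.58 ± 0.09. This list did not pass without the line H1993 (0.15) or H2073 (0.12).

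MUC1, a mucin of the epithelial surface, rose by 0.68 ± 0.06 over the lines. Of 28 epithelial markers, 10 rose, 1 fell and 17 did not pass (10 rose and 1 fell adjusted over the list alone; median 0.17; adjusted p = 0.00225, adjusted p = 0.112 with an estimated correlation). With the line A549 (0.12) or H2073 (0.08) left out the list did not pass. CDH1, the epithelial cadherin, rose in H2073 by 1.07 ± 0.10 and did not pass at -0.02 ± 0.10 in A549 and -0.33 ± 0.10 in H1993 (difference between lines, adjusted p = 6.85e-06). Of 39 neuronal genes, 7 rose, 1 fell and 31 did not pass (7 rose and 1 fell adjusted over the list alone; median 0.22; adjusted p = 0.0471, adjusted p = 0.211 with an estimated correlation), with TUBB3 at 0.47 ± 0.07. The neuronal list no longer passed without any 1 of A549 untreated replicate 1 or 2, A549 Aza-dC replicate 2, H1993 untreated replicate 1, H1993 Aza-dC replicate 2, H2073 untreated replicate 2, H2073 Aza-dC replicate 1 or H2073 Aza-dC/TSA replicate 1 or 2 (adjusted p from 0.0504 to 0.107). Without the line A549 (0.20) or H2073 (0.15) the list did not pass. Of 13 reference genes, 4 rose and 9 did not pass (4 rose adjusted over the list alone; median 0.07; adjusted p = 0.0466, adjusted p = 0.211 with an estimated correlation). That list no longer passed without any 1 of A549 untreated replicate 1, A549 Aza-dC replicate 1 or 2, H1993 untreated replicate 2, H1993 Aza-dC replicate 2, H2073 untreated replicate 2 or H2073 Aza-dC replicate 1 (adjusted p from 0.0508 to 0.123). This list did not pass without the line A549 (0.01). Of 24 NF-kB inflammatory genes, 5 rose and 19 did not pass (5 rose adjusted over the list alone, median 0.22, adjusted p = 0.0628). IL32, a proinflammatory cytokine, was higher by 1.47 ± 0.22. The NF-kB list passed without H1993 untreated replicate 2, H1993 Aza-dC replicate 1 or H2073 Aza-dC replicate 2 (adjusted p from 0.0171 to 0.0433), without the filter (adjusted p = 0.0373) and with it at the 75th percentile (0.0302). With the line A549 (0.41) left out the list passed as higher. Of 19 genes of the lung epithelial lineage, 4 rose, 1 fell and 14 did not pass (4 rose and 1 fell adjusted over the list alone, median 0.19, adjusted p = 0.0859). It passed without H2073 untreated replicate 2 (adjusted p = 0.0311). Without the line H1993 (0.41) the list passed as higher. LAMP3, a surfactant cell marker, rose in H2073 by 3.58 ± 0.24.

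Of 54 genes often methylated in lung cancer, 10 rose, 4 fell and 40 did not pass (11 rose and 4 fell adjusted over the list alone, median 0.13, adjusted p = 0.268). PTPRN2, a member of that list, fell by 1.37 ± 0.17 rather than rose. Of 22 imprinted genes, 4 rose, 3 fell and 15 did not pass (5 rose and 3 fell adjusted over the list alone, median 0.03, adjusted p = 0.583). DIRAS3, a maternally imprinted tumour suppressor, rose (1.79 ± 0.21). Of 26 HOX genes, 3 rose and 23 did not pass (4 rose adjusted over the list alone, median 0.01, adjusted p = 0.740). HOXA2, of the same family, did not pass at -0.17 ± 0.27. Of 41 p53 targets, 11 rose, 5 fell and 25 did not pass (12 rose and 6 fell adjusted over the list alone, median 0.11, adjusted p = 0.168). This list passed as higher without the line H1993 (0.22). CDKN1A, the cell cycle inhibitor p21, rose by 0.36 ± 0.08 and ACTA2 by 0.76 ± 0.08. Of 15 genes of the DNA methylation machinery, 3 rose and 12 did not pass (3 rose adjusted over the list alone, median 0.04, adjusted p = 0.262). With the line H1993 (0.12) left out the list passed as higher. DNMT3A, a de novo methyltransferase, did not pass at 0.00 ± 0.08. Its relative DNMT3B was higher by 0.49 ± 0.14 but did not pass without any 1 of A549 untreated replicate 2, A549 Aza-dC replicate 2, H1993 untreated replicate 1, H1993 Aza-dC replicate 2, H2073 untreated replicate 2 or H2073 Aza-dC replicate 1 (log2 change from 0.39 to 0.48), nor without the line A549 (0.37) or H2073 (0.28). CDKN2A, the tumour suppressor p16, did not pass at -0.11 ± 0.09. Of 11 MHC class II genes, 1 rose, 1 fell and 9 did not pass (2 rose and 1 fell adjusted over the list alone, median 0.31, adjusted p = 0.311). Of 19 histone genes, 4 rose, 2 fell and 13 did not pass (4 rose and 2 fell adjusted over the list alone, median 0.00, adjusted p = 0.940). That list had a mean log2 change of 0.01 and a test direction of down. Of 20 histone deacetylases and partner proteins, 1 rose and 19 did not pass (0 passed adjusted over the list alone by limma, 4 at an unadjusted p under 0.05, median 0.08, adjusted p = 0.444). Of 25 mesenchymal markers, 3 rose and 22 did not pass (4 rose and 1 fell adjusted over the list alone, median 0.09, adjusted p = 0.129). Without the line A549 (0.27) the list passed as higher. Of 15 leukocyte markers, 2 rose and 13 did not pass (2 rose adjusted over the list alone, median 0.17, adjusted p = 0.311). Of 10 fibroblast and endothelial markers, 2 rose, 1 fell and 7 did not pass (2 rose and 1 fell adjusted over the list alone, median 0.10, adjusted p = 0.259). The collagen gene COL1A1, on the last list, rose by 1.53 ± 0.12. Of 25 ribosomal protein genes limma passed 0, with 0 at an unadjusted p under 0.05, a median of 0.04 and adjusted p = 0.740.

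Genes outside the lists rose as well. LY6D, a surface marker of squamous epithelium, rose by 2.53 ± 0.24 over the 3 lines, FCMR, a receptor for IgM, by 1.94 ± 0.25 and PLEKHO1, a casein kinase 2 partner, by 2.45 ± 0.31 (adjusted p = 9.70e-07, 2.82e-05 and 2.67e-05). LY6D was at 3.98 ± 0.41 in A549, 3.57 ± 0.41 in H2073 and 0.04 ± 0.41 in H1993 (difference between lines, adjusted p = 0.000194). By limma, 2161 genes passed for the mean of the lines, 1390 higher and 771 lower, and 210 of them changed at least 2-fold. Camera passed 13 of 27 lists, and 8 of these passed with an estimated correlation as well: cancer-testis antigens, germline genes, interferon response, MHC class I, both cell cycle lists, stress response and heat shock. Only 18 genes passed as higher in each of the 3 lines (1.08 expected if the lines were independent) and 5 as lower (0.211 expected), and 157 passed in opposite directions in different lines.

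In A549 2524 genes passed, 1412 higher and 1112 lower, of which 641 changed at least 2-fold. The deiodinase gene DIO3, from an imprinted locus, rose by 4.15 ± 0.47, CTCFL, the testis paralogue of the insulator protein CTCF, by 4.02 ± 0.51 and the germ cell gene GCNA by 4.09 ± 0.45. TXNIP, an inhibitor of thioredoxin, fell from 3417 ± 79.4 to 394 ± 55.3 (-3.07 ± 0.12) and the stress gene NIBAN1 by 2.89 ± 0.21, whereas TXNIP rose in H2073 (1.45 ± 0.12; difference between lines, adjusted p = 6.58e-12). The count for A549 was 1631 without untreated replicate 1, 1311 without untreated replicate 2, 1188 without Aza-dC replicate 1 and 1516 without Aza-dC replicate 2. In H1993 254 genes passed, 172 higher and 82 lower, of which 100 changed at least 2-fold, beside 2490 at an unadjusted p under 0.05. SERPINB3, a protease inhibitor of squamous epithelium, rose there from 144 ± 66.0 to 862 ± 162 (2.51 ± 0.26) and the neuronal tubulin TUBA1A from 322 ± 9.15 to 690.1 ± 35.0 (1.06 ± 0.12). The count for H1993 was 129 without untreated replicate 1, 124 without untreated replicate 2 and 84 without Aza-dC replicate 1. In H2073 1610 genes passed, 1060 higher and 550 lower, of which 602 changed at least 2-fold, among them the interferon gene XAF1 (4.04 ± 0.47) and GCNA (3.38 ± 0.45). The count for H2073 was 844 without untreated replicate 1, 802 without untreated replicate 2 and 874 without Aza-dC replicate 2. With every array shifted to the same median, which lowered the median of all genes in H2073 from 0.04 to -0.08, the split was 706 higher and 903 lower in H2073, 1524 higher and 775 lower in A549 and 199 higher and 34 lower in H1993.

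After Aza-dC and TSA together, neuronal genes rose. The short-chain dehydrogenase gene DHRS2 went from 633 ± 60.1 to 7269 ± 957 in A549, from 252 ± 0.763 to 2871 ± 526 in H1993 and from 622 ± 57.5 to 3481 ± 189 in H2073 (mean log2 change 3.12 ± 0.10, adjusted p = 1.21e-13). The neuronal pentraxin NPTX2 rose by 3.00 ± 0.22 over the 3 lines, the peptide hormone gene CCK by 2.88 ± 0.14. The tubulins TUBA1A and TUBB2B rose by 2.83 ± 0.07 and 2.74 ± 0.18, the sodium pump regulator FXYD7 by 2.88 ± 0.29 and the GABA transaminase ABAT by 2.77 ± 0.20. Of 39 neuronal genes, 22 rose and 17 did not pass (26 rose adjusted over the list alone), with a median log2 change of 0.76 (adjusted p = 8.82e-09, 0.0109 with an estimated correlation), among them BEX5 (2.24 ± 0.16) and the adhesion molecule L1CAM (1.43 ± 0.11). All 7 measured metallothioneins rose (7 rose adjusted over the list alone; median 0.99; adjusted p = 7.27e-09, 0.0252 with an estimated correlation), with MT1F at 1.27 ± 0.09 and MT1X at 0.93 ± 0.07. WIF1, a secreted Wnt inhibitor often methylated in lung cancer, rose by 2.83 ± 0.24, and PTGDS, the prostaglandin D synthase, by 2.70 ± 0.21. Among the largest falls that had the same sign in every line were those of the death domain gene PIDD1 (-1.77 ± 0.29), the immediate early gene IER5L (-1.66 ± 0.08), the glucocorticoid-induced TSC22D3 (-1.60 ± 0.09) and the adhesion gene ICAM3 (-1.46 ± 0.12).

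Germ cell genes stood above their untreated level in this comparison too. Of 21 cancer-testis antigens, 12 rose, 1 fell and 8 did not pass (14 rose and 1 fell adjusted over the list alone), with a median log2 change of 1.17 (adjusted p = 6.20e-06, 0.00641 with an estimated correlation). MAGEA4 rose in A549 from 12.2 ± 6.11 to 971 ± 248 (5.12 ± 0.46) and SPANXB1 from 62.2 ± 6.39 to 4144 ± 280.0 (5.73 ± 0.42), while MAGEB2 and SSX1 rose over the lines by 1.72 ± 0.18 and 1.30 ± 0.16. The list median was 1.82 in A549 and 1.07 in H2073, and in H1993, where it was 0.37, 3 rose and 2 fell. H1993 was below A549 (adjusted p = 4.90e-05, 0.00542 with an estimated correlation), and H2073 minus H1993 did not pass (adjusted p = 0.0566). Of 20 germline genes under promoter methylation, 11 rose and 9 did not pass (12 rose adjusted over the list alone; median 0.73; adjusted p = 0.000460, 0.0156 with an estimated correlation), among them DAZL (2.37 ± 0.32) and GTSF1 (1.97 ± 0.29).

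Cell cycle genes fell in H1993 alone and stood above untreated cells in A549. CDK1 fell in H1993 from 22910.1 ± 211 to 4644 ± 651 (log2 change -2.31 ± 0.10) and rose in A549 (1.48 ± 0.10) and H2073 (0.47 ± 0.10), a difference between lines with adjusted p = 6.93e-12. All 41 measured G2/M and mitosis genes fell in H1993 (41 fell adjusted over the list alone; median -2.19; adjusted p = 7.83e-53, 0.00614 with an estimated correlation), among them the kinesin KIF2C (-2.65 ± 0.13), the mitotic kinase PLK1 (-2.40 ± 0.19) and the transcription factor FOXM1 (-2.64 ± 0.19). In A549 29 rose, 1 fell and 11 did not pass (31 rose and 1 fell adjusted over the list alone; median 0.75; adjusted p = 2.23e-17, adjusted p = 0.103 with an estimated correlation). In H2073 11 rose and 30 did not pass (15 rose adjusted over the list alone; median 0.38; adjusted p = 2.53e-05, adjusted p = 0.258 with an estimated correlation). The list was lower in H1993 than in A549 (adjusted p = 3.61e-52, 0.00542 with an estimated correlation) and H2073 (adjusted p = 6.71e-53, 0.00611 with an estimated correlation). In the mean of the lines 30 fell and 11 did not pass (33 fell adjusted over the list alone; median -0.35; adjusted p = 1.07e-12, adjusted p = 0.110 with an estimated correlation), but the median turned to 0.55 without H1993. DNA replication and S phase genes went the same way, in that 38 of 39 fell in H1993 (39 fell adjusted over the list alone; median -1.20; adjusted p = 2.80e-34, 0.000922 with an estimated correlation), among them thymidylate synthase TYMS at -2.67 ± 0.10 and RRM2 at -2.24 ± 0.11. In A549 30 rose (32 rose and 1 fell adjusted over the list alone; median 0.79; adjusted p = 1.58e-19, 0.00483 with an estimated correlation). In H2073 13 rose and 26 did not pass (15 rose adjusted over the list alone; median 0.24; adjusted p = 0.000705, adjusted p = 0.164 with an estimated correlation). Over the lines 5 rose, 7 fell and 27 did not pass (5 rose and 9 fell adjusted over the list alone). The list did not pass there (median -0.10, adjusted p = 0.0996), passed as lower without H1993 Aza-dC/TSA replicate 2 (adjusted p = 0.0211) and with every array shifted to the same median (-0.19), as it did without the line A549 (-0.48) or H2073 (-0.22), and turned to 0.50 without H1993. DNMT1 (-0.77 ± 0.11) and UHRF1 (-1.04 ± 0.12) fell in H1993.

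Interferon genes moved in opposite directions in H2073 and H1993. IFI44L fell in H1993 from 523 ± 24.6 to 27.1 ± 3.95 (-3.65 ± 0.30) and rose in H2073 from 94.0 ± 27.9 to 1315 ± 84.8 (3.62 ± 0.30; difference between lines, adjusted p = 1.24e-09). IFIT3 fell in H1993 by 4.26 ± 0.14, and MX1 rose in H2073 by 2.78 ± 0.29. In H1993 25 of 44 interferon genes fell and 5 rose (5 rose and 27 fell adjusted over the list alone; median -0.76; adjusted p = 2.14e-09, 0.00679 with an estimated correlation). In H2073 29 rose and 1 fell (32 rose and 3 fell adjusted over the list alone; median 1.16; adjusted p = 9.19e-16, 0.00429 with an estimated correlation). H2073 differed from H1993 (adjusted p = 2.65e-21, 0.000959 with an estimated correlation), and H1993 from A549, where the median was 0.00 (adjusted p = 4.29e-07, 0.0146 with an estimated correlation). Over the lines 12 rose, 11 fell and 21 did not pass (12 rose and 12 fell adjusted over the list alone; median 0.05; adjusted p = 0.639), and the list passed as lower without H2073 (median -0.52) and as higher without H1993 (median 0.57). For MHC class I and antigen processing, 6 rose, 4 fell and 10 did not pass over the lines (6 rose and 5 fell adjusted over the list alone; median -0.05; adjusted p = 0.810; the test direction was up). In H2073 12 rose (13 rose and 1 fell adjusted over the list alone; median 0.81; adjusted p = 2.01e-09, 0.0179 with an estimated correlation), with PSMB9 at 1.73 ± 0.20. In H1993 6 rose and 8 fell (6 rose and 11 fell adjusted over the list alone), with the immunoproteasome subunit PSMB10 at -2.57 ± 0.19 and HLA-B at 0.67 ± 0.13. H2073 lay above H1993 in this list (adjusted p = 1.43e-09, 0.00907 with an estimated correlation), and the list passed as higher without H1993 (median 0.28) and as lower without H2073 (median -0.38) or without probe sets shared between transcripts (median -0.13). Of 11 MHC class II genes, 7 rose and 4 did not pass (7 rose adjusted over the list alone; median 0.51; adjusted p = 0.00703, adjusted p = 0.0863 with an estimated correlation), HLA-DMA, which loads peptides, among them (0.76 ± 0.11, and 0.27 without H1993, which did not pass). This list did not pass without the line H1993 (0.38) or H2073 (0.21).

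Cholesterol synthesis genes fell. INSIG1, a sterol sensor, fell in H1993 from 1576 ± 193 to 115 ± 53.01 (-3.66 ± 0.22) and in H2073 from 3032 ± 5.30 to 1047 ± 190.3 (-1.53 ± 0.22), and did not pass in A549 (0.44 ± 0.22). There it passed as higher with the mean of its probe sets (0.51) and with A549 fitted alone (0.44). Over the lines 18 fell and 1 did not pass (18 fell adjusted over the list alone; median -0.63; adjusted p = 4.59e-13, 0.00208 with an estimated correlation), with the reductase DHCR7 at -0.91 ± 0.07 and the farnesyl diphosphate synthase FDPS at -0.88 ± 0.07. By line, 17 fell in H1993 (median -1.44), 10 fell in H2073 (median -0.70). In A549 5 rose and 2 fell (median 0.24; adjusted p = 0.0282, adjusted p = 0.157 with an estimated correlation). Both lines lay below A549 (adjusted p = 4.22e-16 and 2.90e-11, and 0.000517 and 0.00432 with an estimated correlation). Without H1993 the median was -0.23 and did not pass. In the stress response list 1 rose, 14 fell and 12 did not pass (1 rose and 16 fell adjusted over the list alone; median -0.30; adjusted p = 1.01e-05, 0.0173 with an estimated correlation), led by A549, where 2 rose and 17 fell (median -0.82). A549 lay below H1993 (adjusted p = 5.41e-05, 0.0204 with an estimated correlation) and H2073 (adjusted p = 9.77e-07, 0.0123 with an estimated correlation). Without A549 the median was -0.02 and did not pass. TRIB3 fell by 1.44 ± 0.06 over the lines, DDIT4 by 0.91 ± 0.06 and the lipoprotein receptor VLDLR by 1.03 ± 0.10. Of 13 heat shock genes, 2 rose, 5 fell and 6 did not pass (3 rose and 6 fell adjusted over the list alone; median -0.08; adjusted p = 0.129). With the line A549 (-0.35) or H2073 (-0.22) left out the list passed as lower. In H1993 9 fell and 4 did not pass (9 fell adjusted over the list alone; median -0.79; adjusted p = 1.33e-07, 0.00544 with an estimated correlation). That was lower than in A549 (adjusted p = 1.43e-06, 0.00542 with an estimated correlation), and the small heat shock protein HSPB1 fell by 0.63 ± 0.08 over the lines.

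Genes often methylated in lung cancer rose more often than they fell. Of 54, 16 rose, 6 fell and 32 did not pass (19 rose and 6 fell adjusted over the list alone; median 0.23; adjusted p = 0.0190, adjusted p = 0.1004 with an estimated correlation). Among those that rose were the Wnt antagonist DKK1 (0.86 ± 0.06) and the basement membrane gene NID2 (1.58 ± 0.14). Without the line H1993 (0.13) the list did not pass. Of 25 mesenchymal markers, 8 rose, 3 fell and 14 did not pass (8 rose and 3 fell adjusted over the list alone; median 0.18; adjusted p = 0.0347, adjusted p = 0.0863 with an estimated correlation), with caveolin CAV1 at 0.93 ± 0.07. This list did not pass without the line H1993 (0.13) or H2073 (0.24). Of 10 fibroblast and endothelial markers, 4 rose and 6 did not pass (4 rose adjusted over the list alone; median 0.50; adjusted p = 0.0347, adjusted p = 0.0968 with an estimated correlation), with COL1A1 at 1.69 ± 0.12. The last list no longer passed without H1993 Aza-dC/TSA replicate 1 (adjusted p = 0.0554) or with quantile normalization (adjusted p = 0.0611). With the line A549 (0.51) or H1993 (0.68) left out the list did not pass. Of 25 ribosomal protein genes, 5 fell and 20 did not pass (4 fell adjusted over the list alone; median -0.15; adjusted p = 0.000501, adjusted p = 0.519 with an estimated correlation). With quantile normalization the median was -0.01 and did not pass. Without the line H2073 (-0.05) the list did not pass. Of 28 epithelial markers, 12 rose, 4 fell and 12 did not pass (12 rose and 5 fell adjusted over the list alone, median 0.14, adjusted p = 0.0673). The epithelial list passed without A549 untreated replicate 2, A549 Aza-dC/TSA replicate 2, H1993 untreated replicate 1, H1993 Aza-dC/TSA replicate 1 or H2073 Aza-dC/TSA replicate 1 (adjusted p from 0.0309 to 0.0443). This list passed as higher without the line H1993 (0.24). KRT19, a keratin of simple epithelium, rose by 0.90 ± 0.09 and CLDN4, a tight junction protein, by 1.14 ± 0.14. Of 19 genes of the lung epithelial lineage, 2 rose, 2 fell and 15 did not pass (1 rose and 2 fell adjusted over the list alone, median 0.13, adjusted p = 0.414). LAMP3 rose by 2.04 ± 0.14. Of 15 leukocyte markers, 2 rose and 13 did not pass (2 rose adjusted over the list alone, median 0.20, adjusted p = 0.233).

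Of 41 p53 targets, 12 rose, 5 fell and 24 did not pass (12 rose and 5 fell adjusted over the list alone, median 0.09, adjusted p = 0.268). GDF15, a stress cytokine, fell by 1.15 ± 0.07, the lysosomal fucosidase FUCA1 rose by 0.83 ± 0.07 and CDKN1A did not pass at 0.10 ± 0.08, but passed without A549 (0.32). Of 19 histone genes, 5 rose, 3 fell and 11 did not pass (5 rose and 3 fell adjusted over the list alone, median 0.04, adjusted p = 0.639). The linker histone gene H1-2 rose by 0.80 ± 0.09 and H2BC21 by 1.15 ± 0.11. Of 15 genes of the DNA methylation machinery, 3 rose and 12 did not pass (3 rose adjusted over the list alone, median 0.10, adjusted p = 0.227). With the line H1993 (0.25) left out the list passed as higher. The thymine DNA glycosylase TDG rose by 0.53 ± 0.09. Of 20 histone deacetylases and partner proteins, 2 rose, 4 fell and 14 did not pass (2 rose and 4 fell adjusted over the list alone, median -0.10, adjusted p = 0.504). HDAC1 fell by 0.34 ± 0.06. Of 22 imprinted genes, 4 rose, 1 fell and 17 did not pass (4 rose and 1 fell adjusted over the list alone, median 0.08, adjusted p = 0.504). DIRAS3 rose by 1.84 ± 0.21. Of 26 HOX genes, 2 rose, 1 fell and 23 did not pass (1 fell adjusted over the list alone, median 0.03, adjusted p = 0.947). Of 13 reference genes, 2 rose, 1 fell and 10 did not pass (2 rose and 5 fell adjusted over the list alone, median -0.08, adjusted p = 0.504). Of 24 NF-kB inflammatory genes, 6 rose, 2 fell and 16 did not pass (7 rose and 2 fell adjusted over the list alone, median 0.16, adjusted p = 0.227). Without the line A549 (0.29) the list passed as higher. The chemokine CCL20 rose by 3.69 ± 0.41 in A549 and IL32 by 1.64 ± 0.22 over the lines.

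By limma, 4648 genes passed for the mean of the lines, 2441 higher and 2207 lower, and 543 changed at least 2-fold. Camera passed 12 of 27 lists, 6 of them also with an estimated correlation. Genes that passed as higher in each of the 3 lines numbered 159 (31.2 expected if the lines were independent) and as lower 152 (22.3 expected), and 1319 passed in opposite directions. In A549 4124 genes passed, 1917 higher and 2207 lower, of which 1127 changed at least 2-fold. Among them were the neurofilament gene NEFH (4.63 ± 0.45), cyclin CCNA1 (4.51 ± 0.46), TXNIP (-3.33 ± 0.12) and the syntrophin SNTB1 (-2.71 ± 0.23). That count was 2479 without untreated replicate 2, 2601 without Aza-dC/TSA replicate 1 and 2655 without Aza-dC/TSA replicate 2. In H1993 4433 genes passed, 2488 higher and 1945 lower, of which 1759 changed at least 2-fold. The secretory granule gene SCG5 rose there from 9.36 ± 0.0645 to 1089 ± 30.8 (5.44 ± 0.24), as did the hormone subunit gene CGA (4.41 ± 0.34) and APLP1, a relative of the amyloid precursor (4.81 ± 0.33). In H2073 2789 genes passed, 1555 higher and 1234 lower, of which 853 changed at least 2-fold. Among them were suprabasin SBSN (4.07 ± 0.44), the ubiquitin-conjugating gene UBE2QL1 (3.87 ± 0.50), the RNA-binding protein RBPMS2 (3.85 ± 0.25), the membrane protein TM4SF4 (-2.95 ± 0.21) and the transcription factor SOX8 (-2.87 ± 0.61). That count was 1712 without untreated replicate 1, 1674 without untreated replicate 2 and 1582 without Aza-dC/TSA replicate 1. With every array shifted to the same median, which moved the median of all genes in H1993 from 0.07 to -0.16, the split was 1464 higher and 3336 lower in H1993, 1158 higher and 1544 lower in H2073 and 1643 higher and 3238 lower for the mean.

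**Figure D2:**
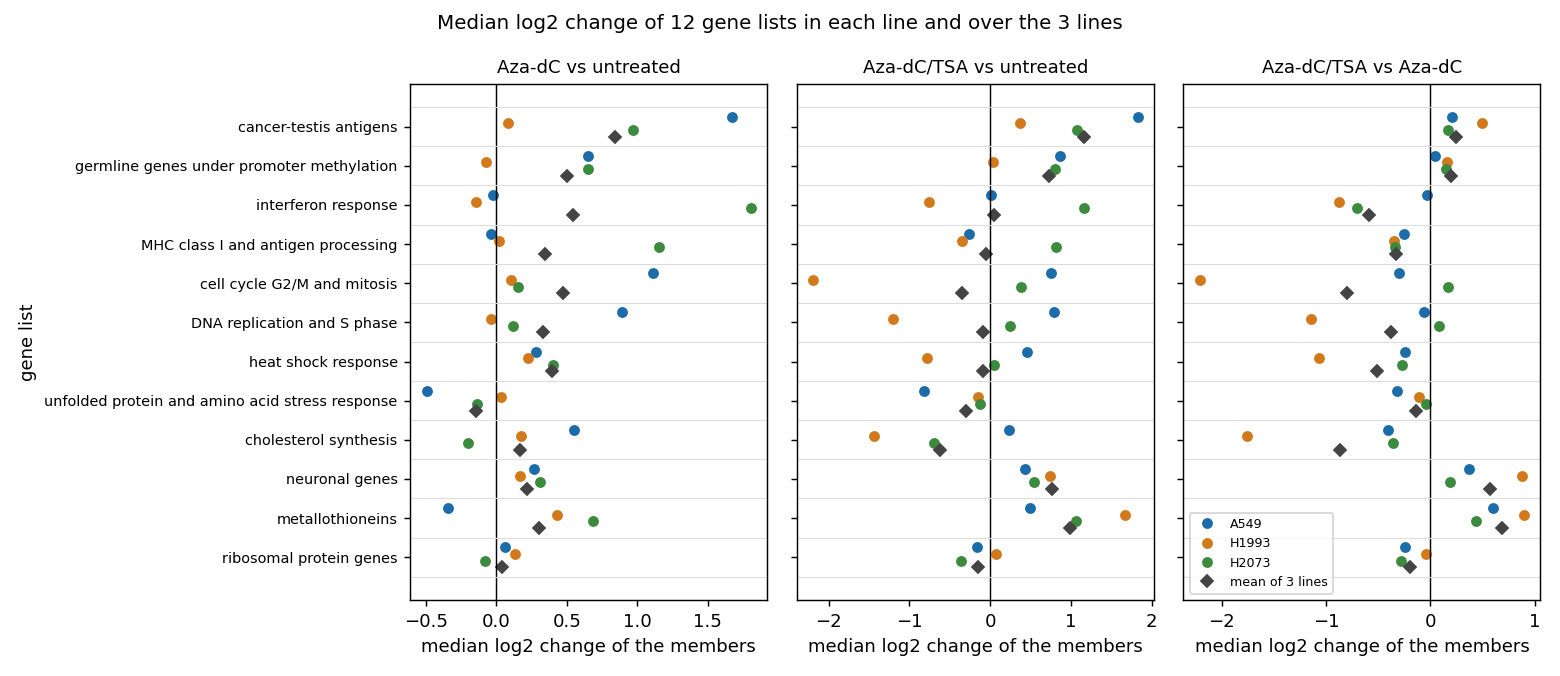
Median log2 change of the members of 12 gene lists (horizontal axis, log2) in A549, H1993 and H2073 (circles) and averaged over the 3 lines per member (diamonds). The G2/M list lay at 1.12 in A549 with Aza-dC and at -2.19 in H1993 with Aza-dC/TSA.

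Aza-dC/TSA was also compared with Aza-dC alone. The TSA arm ran 24 h longer, and TSA alone was not analysed here. DHRS2 rose by 2.80 ± 0.10 over the lines (adjusted p = 1.76e-12). The sodium pump subunit ATP1B2 rose by 2.68 ± 0.27, the GABA receptor subunit GABRD by 2.50 ± 0.27, the complement regulator SUSD4 by 2.42 ± 0.33, the Notch ligand DNER by 2.26 ± 0.12, ABAT by 2.27 ± 0.20 and the melanosome gene PMEL by 2.13 ± 0.21. Of 39 neuronal genes, 18 rose and 21 did not pass (18 rose adjusted over the list alone; median 0.57; adjusted p = 8.68e-07, 0.0148 with an estimated correlation), among them L1CAM (1.44 ± 0.11) and BEX5 (1.73 ± 0.16). All 7 metallothioneins rose (7 rose adjusted over the list alone; median 0.69; adjusted p = 4.51e-07, 0.0463 with an estimated correlation), with MT1H at 0.71 ± 0.08. Cholesterol synthesis genes fell. Of 19, 17 fell and 2 did not pass (18 fell adjusted over the list alone; median -0.87; adjusted p = 6.19e-18, 0.000638 with an estimated correlation), with ACAT2 at -1.50 ± 0.07, INSIG1 at -1.56 ± 0.13 and DHCR7 at -1.08 ± 0.07. Of 13 heat shock genes, 11 fell and 2 did not pass (12 fell adjusted over the list alone; median -0.51; adjusted p = 3.92e-09, 0.00387 with an estimated correlation), with HSPB1 at -1.03 ± 0.08 and HSPH1 at -0.71 ± 0.07. MICB, a stress-induced ligand of natural killer cells, fell by 1.36 ± 0.10.

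Cell cycle genes fell in the mean of the lines. All 41 G2/M and mitosis genes fell (41 fell adjusted over the list alone; median -0.79; adjusted p = 4.82e-38, 0.0143 with an estimated correlation). The list median was -2.21 in H1993 (adjusted p = 9.01e-52, 0.00658 with an estimated correlation). It was -0.30 in A549 (adjusted p = 4.14e-10, adjusted p = 0.219 with an estimated correlation) and 0.17 in H2073 (adjusted p = 0.00441, adjusted p = 0.559 with an estimated correlation). In H1993 KIF2C fell by 2.74 ± 0.13 and TYMS by 2.53 ± 0.10. Of 39 DNA replication and S phase genes, 30 fell and 9 did not pass (33 fell adjusted over the list alone; median -0.38; adjusted p = 7.96e-17, 0.00669 with an estimated correlation), and without H1993 the median was -0.02 and did not pass. Interferon genes also fell. Of 44, 3 rose, 26 fell and 15 did not pass (4 rose and 28 fell adjusted over the list alone; median -0.58; adjusted p = 1.59e-10, 0.00669 with an estimated correlation). IFI35 fell by 1.15 ± 0.09. Of 20 genes of MHC class I and antigen processing, 2 rose, 11 fell and 7 did not pass (2 rose and 12 fell adjusted over the list alone; median -0.33; adjusted p = 6.86e-05, adjusted p = 0.0634 with an estimated correlation), with TAP1 at -1.31 ± 0.09 and PSMB10 at -1.24 ± 0.11. Of 11 MHC class II genes, 4 rose and 7 did not pass (4 rose adjusted over the list alone; median 0.42; adjusted p = 0.0436, adjusted p = 0.201 with an estimated correlation). That list no longer passed without any 1 of A549 Aza-dC replicate 2, A549 Aza-dC/TSA replicate 1, H1993 Aza-dC/TSA replicate 2, H2073 Aza-dC replicate 2 or H2073 Aza-dC/TSA replicate 1 or 2 (adjusted p from 0.0508 to 0.113) or with quantile normalization (adjusted p = 0.108). This list did not pass without the line H1993 (0.22) or H2073 (0.30). Of 25 ribosomal protein genes, 12 fell and 13 did not pass (17 fell adjusted over the list alone; median -0.19; adjusted p = 6.86e-05, adjusted p = 0.469 with an estimated correlation). Of 13 reference genes, 8 fell and 5 did not pass (8 fell adjusted over the list alone; median -0.21; adjusted p = 0.0374, adjusted p = 0.222 with an estimated correlation). With quantile normalization both lists ended near 0 (medians -0.01 and -0.05) and did not pass, and the reference list also failed without A549 Aza-dC/TSA replicate 2, H1993 Aza-dC replicate 2, H1993 Aza-dC/TSA replicate 1 or H2073 Aza-dC replicate 1 (adjusted p from 0.0509 to 0.0620). With the line H2073 (-0.14) left out the list did not pass.

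Of 54 genes often methylated in lung cancer, 14 rose, 6 fell and 34 did not pass (14 rose and 7 fell adjusted over the list alone, median 0.03, adjusted p = 0.0747). DKK1 rose by 0.81 ± 0.06. The list passed without H1993 Aza-dC replicate 2 or H2073 Aza-dC replicate 1 (adjusted p from 0.0463 to 0.0480), and with every array shifted to the same median it passed at a median of -0.07. Without the line H2073 (0.13) the list passed as higher. Of 21 cancer-testis antigens, 2 rose, 1 fell and 18 did not pass (1 fell adjusted over the list alone, median 0.25, adjusted p = 0.303). Of 20 germline genes under promoter methylation, 1 rose, 1 fell and 18 did not pass (1 rose adjusted over the list alone, median 0.20, adjusted p = 0.322). Of 27 stress response genes, 4 rose, 9 fell and 14 did not pass (4 rose and 10 fell adjusted over the list alone, median -0.13, adjusted p = 0.112). They passed as lower with every array shifted to the same median (-0.23). This list passed as lower without the line H1993 (-0.19). Of 19 histone genes, 7 rose, 5 fell and 7 did not pass (8 rose and 5 fell adjusted over the list alone, median 0.08, adjusted p = 0.658). H1-2 rose by 0.95 ± 0.09. Of 22 imprinted genes, 3 rose, 3 fell and 16 did not pass (3 rose and 3 fell adjusted over the list alone, median 0.02, adjusted p = 0.908). Of 26 HOX genes, 2 fell and 24 did not pass (1 fell adjusted over the list alone, median -0.01, adjusted p = 0.855). With the line H1993 (-0.23) left out the list passed as lower. Of 41 p53 targets, 6 rose, 6 fell and 29 did not pass (6 rose and 6 fell adjusted over the list alone, median -0.06, adjusted p = 0.867). Of 15 genes of the DNA methylation machinery, 3 rose, 3 fell and 9 did not pass (3 rose and 5 fell adjusted over the list alone, median 0.02, adjusted p = 0.867). Of 20 histone deacetylases and partner proteins, 1 rose, 4 fell and 15 did not pass (1 rose and 5 fell adjusted over the list alone, median -0.07, adjusted p = 0.303). Of 28 epithelial markers, 3 rose, 7 fell and 18 did not pass (3 rose and 7 fell adjusted over the list alone, median -0.05, adjusted p = 0.723). Of 25 mesenchymal markers, 5 rose, 2 fell and 18 did not pass (5 rose and 2 fell adjusted over the list alone, median 0.11, adjusted p = 0.149). Of 19 genes of the lung epithelial lineage, 1 rose, 2 fell and 16 did not pass (1 rose and 2 fell adjusted over the list alone, median -0.13, adjusted p = 0.723). Of 15 leukocyte markers, 1 rose, 1 fell and 13 did not pass (0 passed adjusted over the list alone by limma, 3 at an unadjusted p under 0.05, median 0.15, adjusted p = 0.694). Of 10 fibroblast and endothelial markers, 2 rose and 8 did not pass (2 rose adjusted over the list alone, median 0.14, adjusted p = 0.318). Of 24 NF-kB inflammatory genes, 2 rose, 4 fell and 18 did not pass (2 rose and 4 fell adjusted over the list alone, median -0.03, adjusted p = 0.908). Its mean was 0.01 and its test direction down.

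By limma, 4195 genes passed for the mean of the lines, 1938 higher and 2257 lower, and 254 changed at least 2-fold. Camera passed 11 lists, 7 of them also with an estimated correlation. In H1993 4721 genes passed, 2513 higher and 2208 lower, of which 1855 changed at least 2-fold. In A549 1103 genes passed, 410 higher and 693 lower, of which 145 changed at least 2-fold. In H2073 581 genes passed, 258 higher and 323 lower, of which 102 changed at least 2-fold. The difference between lines was not tested for this comparison. The A549 count was 379 without Aza-dC replicate 1, 170 without Aza-dC replicate 2, 196 without Aza-dC/TSA replicate 1 and 266 without Aza-dC/TSA replicate 2, and the H2073 count 127 without Aza-dC replicate 1 and 206 without Aza-dC/TSA replicate 1. Genes that passed as higher in each line numbered 40 (1.12 expected) and as lower 67 (2.08 expected), and 136 passed in opposite directions. With every array shifted to the same median, the median of all genes moved from 0.07 to -0.24 in H1993 and from 0.00 to -0.10 for the mean. The split was then 1291 higher and 4271 lower in H1993, 220 higher and 141 lower in H2073 and 1156 higher and 3340 lower for the mean.

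The lines differed in which genes moved. Tested as an interaction in limma, 2392 genes changed differently between lines with Aza-dC, TXNIP (adjusted p = 6.58e-12), the interferon gene IFIT1 (1.94e-08) and TRIB3 (3.10e-08) among those with the lowest p, and 5434 with Aza-dC/TSA, IFIT3 (6.93e-12), CDK1 (6.93e-12), TUBA1A (7.71e-12) and RRM2 (3.34e-11) among them. The first of these counts was 1556 without A549 untreated replicate 2 and 1358 without A549 Aza-dC replicate 1. Genes higher with Aza-dC in both A549 and H2073 numbered 231 (97.1 expected by chance, Fisher's exact test adjusted p = 3.28e-38). In both H1993 and H2073 they numbered 44 (11.8 expected, adjusted p = 1.66e-14) and in both A549 and H1993 40 (15.8 expected, adjusted p = 3.07e-08). With Aza-dC/TSA the same pairs of lines shared 512 (193 expected, adjusted p = 1.91e-112), 473 (251 expected, adjusted p = 9.26e-50) and 379 (309 expected, adjusted p = 7.11e-06). These p were adjusted over a family of 18 two-sided tests, and genes are not independent of each other.

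**Figure D3:**
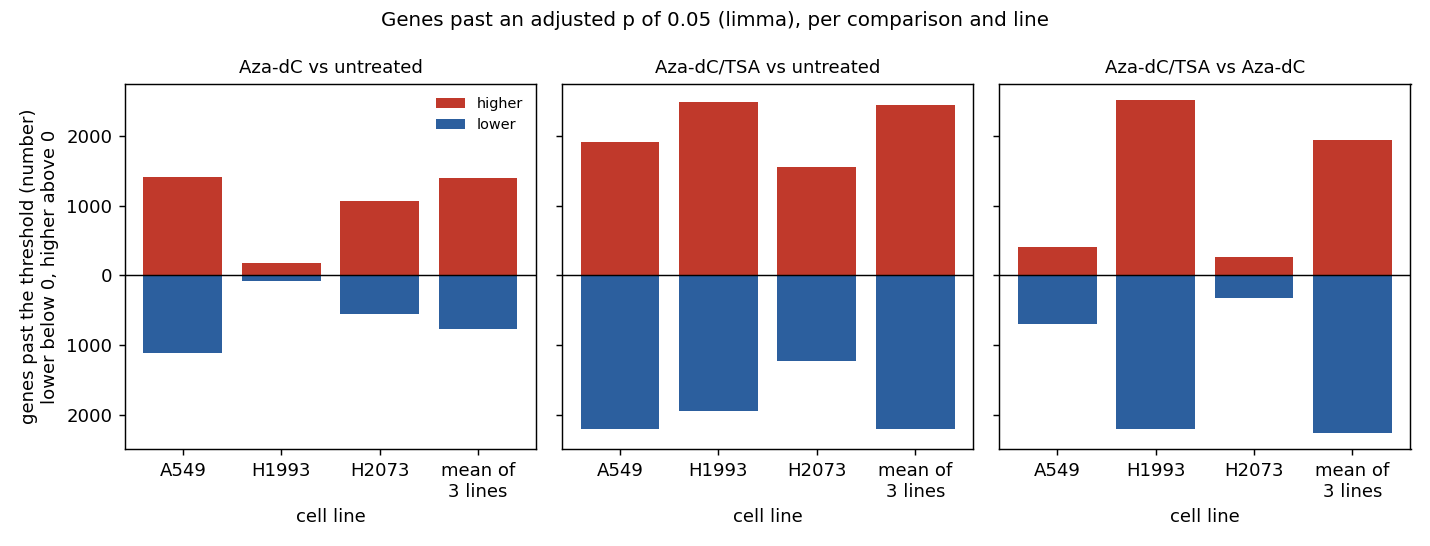
Number of genes past an adjusted p of 0.05 in limma (vertical axis, genes), higher above 0 and lower below 0, per comparison in each line and for the mean of 3 lines. With Aza-dC 254 genes passed in H1993 against 2524 in A549.

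The changes with Aza-dC and with Aza-dC/TSA were measured against the same untreated arrays, which alone makes them correlate. Across genes Pearson's r of the mean changes was 0.548. It was 0.498 in 20 simulations without any effect and 0.347 when each comparison had its own untreated replicate. The covariance was 0.0765 against 0.0203 in the simulations and 0.0559 with separate replicates. In the 2 comparisons 718 genes were higher in both, 394 lower in both and 177 in opposite directions. MAGEB2, DIRAS3 and COL1A1 were among the shared rises and DDIT4 among the shared falls.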

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

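The tests of the H1993 response, of the cell cycle genes and of the interferon genes were chosen only after the results they concern were seen. TXNIP, TRIB3, IFIT1, CMPK2 and the membrane protein gene AMIGO2 had the lowest p among the 2392 genes whose change with Aza-dC differed between lines (adjusted p = 6.58e-12, 3.10e-08, 1.94e-08, 3.10e-08 and 3.10e-08). With Aza-dC/TSA 5434 genes differed, TXNIP (adjusted p = 2.85e-13), IFIT3 (6.93e-12), CDK1 (6.93e-12), TUBA1A (7.71e-12) and RRM2 (3.34e-11) first. Of the 27 lists, with Aza-dC 12 (6 with an estimated correlation) differed between H1993 and A549, 15 (5 with an estimated correlation) between H2073 and A549 and 12 (4 with an estimated correlation) between H2073 and H1993. With Aza-dC/TSA these were 13 (7 with an estimated correlation), 13 (7 with an estimated correlation) and 7 (6 with an estimated correlation). The count of 2392 was 1556 without A549 untreated replicate 2 and 1358 without A549 Aza-dC replicate 1.

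Signals also appeared outside the genes tested. For the mean of the lines 6618 probe sets with several gene symbols or none were tested. With Aza-dC 286 passed (181 higher), with Aza-dC/TSA 1100 (748 higher) and from Aza-dC to Aza-dC/TSA 1036 (710 higher).

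Arrays were regrouped, 2 against 2 within each line, in 100 splits drawn with a fixed seed. For genes passing for the mean of the lines, only the real split reached its count. With Aza-dC it was 2161 against at most 1888 in any other, with Aza-dC/TSA 4648 against 4570. From Aza-dC to Aza-dC/TSA it was 4195 against 3775. The 11 lists from Aza-dC to Aza-dC/TSA were tied (highest other 11, 2 splits). Those with Aza-dC, 13 (highest other 14, 7 splits), and Aza-dC/TSA, 12 (highest other 13, 9 splits), were exceeded. Replicates may be technical, so chance differences between cultures cannot be excluded. Splits that exchange both groups of a whole line keep the treatment effect of that line, a structure of the samples that raises the other counts.

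The first pattern is the small response of H1993 to Aza-dC, in which 254 genes passed (129 without untreated replicate 1, 124 without untreated replicate 2 and 84 without Aza-dC replicate 1). If the Aza-dC arrays of H1993 held untreated cells, the 231 genes that rose in both other lines, MAGEA4 and GCNA among them, should not move there. Their median log2 change was 0.107 and 0.141 on these arrays, against 0.975 in A549 and 0.966 in H2073. Random genes of the same level reached 0.0803 and 0.0788 (95 percent range), which leaves out differences between cultures, so a wrong label stays open. A larger spread between arrays is argued against. The SD of the changes after subtracting replicate variance was 0.481 times that of H2073 (95 percent bootstrap range 0.432 to 0.526). A weaker uptake or action of Aza-dC in this line may explain the small response. That stays untested, as does a dose that differed from the one worded for A549.

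The second pattern is the rise of cell cycle genes in A549 with Aza-dC, such as CDK1 and CCNB1. Scaling that depends on brightness is argued against: the list median was 1.12, against -0.10 to 0.16 for 95 percent of random lists matched on level, and 1.14 after quantile normalization. The growth state of the untreated A549 cultures and an effect of Aza-dC cannot be told apart, because both comparisons with untreated A549 use the same 2 arrays, and the comparison of Aza-dC/TSA with Aza-dC holds no untreated cells. Those arrays differed from each other by 0.162 in the cell cycle list and -0.105 in the stress list, and Aza-dC/TSA stood above them too (0.75). Untreated cells that had grown denser, with fewer dividing cells and more TRIB3, could give the rise of the cell cycle list and the fall of the stress list (-0.496) without any action of Aza-dC on these genes.

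The third pattern is the rise of interferon genes such as MX1 and IFI44L in H2073 with Aza-dC and their fall in H1993 with Aza-dC/TSA. Scaling between arrays is argued against, since after quantile normalization the list median was -0.940 in H1993 and 1.82 in H2073. So is 1 aberrant array: the median was -0.843 and -0.921 on the Aza-dC/TSA arrays of H1993 and 1.69 and 1.87 on the Aza-dC arrays of H2073. The 23 members that started lower in untreated H1993 than in untreated H2073 fell as well (median -0.641, 95 percent bootstrap range -1.15 to -0.0948). Chosen as such, they cannot test a higher starting level. The 21 members that started higher, MX1 and IFI44L among them, fell by a median of 1.25. That differed from the others by -0.610 (range -1.23 to 0.402, which includes 0), so that for these members the starting level and a response to treatment cannot be told apart. A response to demethylated repeats in H2073 is a candidate explanation that was not tested, and because the lines come from 1 patient, a difference acquired by the tumour or in culture stays open.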

How the results depend on the processing

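Results were computed again under the processing alternatives that could be applied to them, changing 1 choice at a time. A gene or list that an alternative left out has no value there. With TSA added stands for Aza-dC/TSA against Aza-dC. All alternatives were chosen before the results were seen, and the cause of a change was not tested unless it is given. TXNIP, CDK1, MX1 and DHRS2 passed as reported under every alternative that could be applied to them. Of the values of single genes named, 5081 kept their direction and side of the threshold, 9 no longer passed and 3 passed only in the alternative, all of them DNMT3B with Aza-dC, HLA-DMA, CDKN1A or INSIG1 with Aza-dC/TSA. Because genes with stable calls were preferred as examples, these numbers say little about other genes. For the lists, 4989 values kept both, 290 no longer passed, 38 newly passed and 11 reversed. Of the counts, 455 stayed within 1.5 times the reported count, 49 fell below and 2 rose above it.

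With every array shifted to the same median, 361 genes passed with TSA added in H2073 in place of 581. Without probe sets shared between transcripts (12467 genes tested), 1681 genes passed with Aza-dC in A549 in place of 2524, 586 genes passed with TSA added in A549 in place of 1103 and 1070 genes passed with Aza-dC in H2073 in place of 1610. Likewise, 1841 passed with Aza-dC/TSA in H2073 in place of 2789 and 358 with TSA added in H2073 in place of 581. Genes differing between lines with Aza-dC were 1505 in place of 2392. For the mean, 7 lists passed with TSA added in place of 11. Without an intensity trend in the variance, 389 genes passed with TSA added in A549 in place of 1103, 88 genes passed with Aza-dC in H1993 in place of 254, 196 genes passed with TSA added in H2073 in place of 581 and 1437 genes differed between lines with Aza-dC in place of 2392. Fitted on the 6 arrays of a line alone, 4030 genes passed with Aza-dC in A549 in place of 2524, 2528 genes passed with TSA added in A549 in place of 1103 and 40 genes passed with Aza-dC in H1993 in place of 254. Likewise, 938 genes passed with Aza-dC in H2073 in place of 1610 and 147 genes passed with TSA added in H2073 in place of 581, where the spread came from fewer arrays. Averaged over the lines other than A549, 1072 genes passed with Aza-dC for the mean in place of 2161 and 8 lists passed with Aza-dC for the mean in place of 13. Averaged over the lines other than H1993, 1832 genes passed with TSA added for the mean in place of 4195. Averaged over the lines other than H2073, 8 lists passed with Aza-dC for the mean in place of 13. With an estimated correlation, 8 lists passed with Aza-dC for the mean in place of 13, 6 lists passed with Aza-dC/TSA for the mean in place of 12 and 7 lists passed with TSA added for the mean in place of 11.

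Without probe sets shared between transcripts, the direction of the list test reversed for heat shock response with TSA added in A549 (median 0.0686, reported -0.25) and MHC class I and antigen processing with Aza-dC/TSA for the mean (median -0.13, reported -0.05). Without H2073 Aza-dC replicate 2, it reversed for ribosomal protein genes with Aza-dC in H2073 (median 0.0657, reported -0.08). Averaged over the lines other than A549, it reversed for cholesterol synthesis with Aza-dC for the mean (median -0.0276, reported 0.17). Averaged over the lines other than H1993, it reversed for cell cycle G2/M and mitosis with Aza-dC/TSA for the mean (median 0.55, reported -0.35), DNA replication and S phase with Aza-dC/TSA for the mean (median 0.50, reported -0.10) and DNA replication and S phase with TSA added for the mean (median -0.0157, reported -0.38). Averaged over the lines other than H2073, it reversed for interferon response with Aza-dC for the mean (median -0.0808, reported 0.54), MHC class I and antigen processing with Aza-dC for the mean (median -0.0351, reported 0.34), interferon response with Aza-dC/TSA for the mean (median -0.52, reported 0.05) and MHC class I and antigen processing with Aza-dC/TSA for the mean (median -0.38, reported -0.05).

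Calls of lists for the mean of the lines also changed as follows. With quantile normalization, calls were lost for reference with Aza-dC and made for epithelial with Aza-dC/TSA. With no filter, calls were lost for MHC class II with TSA added and made for NF-kB with Aza-dC; epithelial with Aza-dC/TSA. With the filter at the 75th percentile, calls were lost for germline, neuronal, reference with Aza-dC; mesenchymal with Aza-dC/TSA; reference with TSA added and made for NF-kB with Aza-dC; often methylated with TSA added. With 1 added in place of 16, calls were lost for neuronal with Aza-dC; MHC class II with TSA added. With 64 added, calls were lost for neuronal with Aza-dC; mesenchymal, fibroblast with Aza-dC/TSA. With the mean of the probe sets of a gene, calls were lost for reference with Aza-dC; mesenchymal with Aza-dC/TSA; ribosomal, reference with TSA added. With no shared probe sets, calls were lost for neuronal, cholesterol with Aza-dC; MHC class II, often methylated, mesenchymal, fibroblast, ribosomal with Aza-dC/TSA; MHC class II, ribosomal, reference with TSA added and made for epithelial with Aza-dC/TSA.

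With the replicate number as a block, 727 genes passed with TSA added in A549 in place of 1103, 119 genes passed with Aza-dC in H1993 in place of 254 and 276 genes passed with TSA added in H2073 in place of 581. The block had nothing to remove, since replicates of different groups with the same number did not share their deviations (r from -0.125 to 0.0271).

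Each array was left out in turn, with the lone array of its group assumed to vary like the other groups. The count of genes ranged, for Aza-dC in A549 1188 to 2708 (lowest without A549 Aza-dC replicate 1), Aza-dC/TSA in A549 2479 to 4330 (lowest without A549 untreated replicate 2) and TSA added in A549 170 to 1324 (lowest without A549 Aza-dC replicate 2). It ranged for Aza-dC in H1993 84 to 331 (lowest without H1993 Aza-dC replicate 1), Aza-dC/TSA in H1993 3265 to 4593 and TSA added in H1993 3474 to 4927. It ranged for Aza-dC in H2073 802 to 1774 (lowest without H2073 untreated replicate 2), Aza-dC/TSA in H2073 1582 to 2946 (lowest without H2073 Aza-dC/TSA replicate 1) and TSA added in H2073 127 to 718 (lowest without H2073 Aza-dC replicate 1). Over the lines it ranged for Aza-dC for the mean 1581 to 2311, Aza-dC/TSA for the mean 3842 to 4774, TSA added for the mean 3380 to 4352, Aza-dC differing between lines 1358 to 2699 (lowest without A549 Aza-dC replicate 1) and Aza-dC/TSA differing between lines 4437 to 5568. The count of lists ranged for Aza-dC for the mean 11 to 14, Aza-dC/TSA for the mean 12 to 13 and TSA added for the mean 10 to 11. The median of the ribosomal protein genes with Aza-dC in H2073 ranged from -0.224 to 0.0657.

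Signal over background limits what can be seen: the filter on signal set the number of genes tested, 19775 without it and 9992 at the 75th percentile of each array, and genes near the floor of the arrays have changes compressed by the 16 units added before the logarithm.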

Other observations

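The tests of genes low in 1 line and of neighbouring genes were chosen before their results were seen. EPCAM, an epithelial adhesion molecule, was lower in untreated A549 (1359.6 ± 264, mean ± SD of n = 2 arrays) than in H1993 (19809.9 ± 434) and H2073 (21205 ± 802), and with Aza-dC it rose in A549 to 4152 ± 313 (log2 change 1.61 ± 0.13). CAV1, which coats caveolae, was likewise low in H2073 (1647 ± 162) and rose there to 3939 ± 10.6 (1.25 ± 0.11), whereas CDKN2A, which is known to be deleted in A549, was at -0.06 ± 0.15 in that line. For genes at least 2 log2 units lower in 1 untreated line than in both others, the group was chosen on 1 untreated array and the rise taken against the other. The median log2 rise with Aza-dC was 0.336 for 351 genes in A549 (95 percent range of other genes -0.0542 to 0.0857). It was 0.112 for 414 genes in H1993 (range -0.0904 to 0.0415) and 0.581 for 158 genes in H2073 (range 0.0550 to 0.293). Each lay above random genes of the same level in that line, which is consistent with release of a silencing that was particular to the line. Methylation of these genes was not analysed here, so that other causes, such as the shift of cell cycle genes like MCM4 in A549, stay open.

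Neighbouring genes rose together with Aza-dC somewhat more often than random placement gives. Among 12450 genes, of which 920 had risen for the mean of the lines, 88 pairs of neighbours had both risen, against 67.8 expected (95 percent range 53 to 83), with probe sets that may be shared between transcripts left out. For genes that fell, 37 pairs were found (range 20 to 40), within chance. Release of silencing over a region may explain the excess, and families of related genes that lie side by side, such as the metallothioneins and MAGE genes, could give it as well.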
